A study of Homo sapiens with 24 samples.

How the data were processed

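RNA was measured in 24 libraries from HMEC-1 cells, 4 for each of 6 groups: infected and uninfected wells at 4, 24 and 48 h after Borrelia burgdorferi was added at 200 bacteria per cell. Per the labels, cells had been seeded 28, 48 or 72 h before collection, so later time points are also older cultures. Groups and times were taken from the sample titles. The treatment protocol in the labels gives a shorter last exposure and, in its next sentence, an earlier first collection, so those times are not certain. The replicate letters A to D recur in each group, and nothing in the labels says that a letter marks a shared culture or day, nor that replicates are separate cultures, so the p-values measure only the spread between these libraries.

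Reads were handled with cutadapt, HISAT2 and StringTie against GRCh37, per the submitters' processing notes, which give no versions, settings or order. The authors deposited a gene table and a transcript table in FPKM, fragments scaled to transcript length and library size, per the file headers; any further scaling between libraries is not stated. The gene table holds 11422 genes and 32815 transcripts are listed in the other, all protein-coding, each with a mean FPKM of at least 0.5 in at least 1 group as tested on the values. Genes outside these tables were not analysed here. The authors also deposited lists of changed genes and transcripts for 6 comparisons. The authors' deposited log2 fold changes in them were computed as differences between group means of log2(FPKM + 1), as tested on the values. The authors' deposited p-values and q-values were made with a test that is not named, per the file headers. Every listed gene had an unadjusted p-value of at most 0.0497 and an absolute log2 fold change of at least 0.585. These deposited lists were used only to count overlap, and 9 stray entries that follow a blank line in 1 list were not used. The 192 columns of per-sample FPKM in the deposited lists were left out, because the main tables already give those libraries.

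Depth is unknown: the deposited values are FPKM, no read totals are given, and the design text names only a target number of reads per sample, in pairs of 150 bases. No interval that needs read counts is therefore given, and precision is shown by the spread between libraries. Within-group Pearson correlations of log2 values across genes ranged from 0.970 to 0.986.

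Tests used log2(FPKM + 0.5) for genes with an FPKM of at least 1 in at least 4 of the 24 libraries, which left 10517 genes, and 25667 transcripts by the same rule. One linear model with a mean per group was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), so that all groups share the estimate of the spread per gene. The 9 gene comparisons were infected against uninfected wells at each time, 24 h and 48 h against 4 h within infected and within uninfected wells, and the difference between these changes (infection by time). The 3 infection comparisons were repeated for transcripts. Tests were two-sided, and a gene or transcript passed with a Benjamini-Hochberg adjusted p under 0.05. Values are given as group mean ± SD of FPKM with n = 4, and log2 fold changes with the limma standard error where one is printed.

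The rule for named genes took, for each infection comparison, the 12 genes with the largest rise and the 12 with the largest fall among those that passed, with a mean FPKM of at least 2 in the higher group and no overlap between the 4 and 4 libraries. For the time comparisons and infection by time it took 6 each way, without the non-overlap condition for the latter. Up to 4 members with the smallest adjusted p were added for each gene list with members that passed, and CXCL8, CCL2, IL6, SELE, ICAM1, VCAM1, NFKBIA, TNFAIP3, CDH5, PECAM1, VWF, CTGF, FN1, GAPDH and ACTB were always eligible. SELE and PECAM1 were not analysed here, and some genes that met the rule are not reported here. Clone-based and uncharacterised names, small RNA genes, pseudogenes, Y-linked genes and XIST were passed over. The tests, this rule, 27 gene lists and most alternatives were chosen before the data were examined. Genes and 6 further lists chosen after values were seen are named as such.

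Gene lists were tested with camera in limma, which compares the members of a list with all other genes, with its preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the data. Its p-values were Benjamini-Hochberg adjusted over the lists of each comparison. For lists among these 27, the number of members that passed is given with adjustment over all genes and, in those words, adjusted over the list alone. Shares of a library's FPKM were compared with two-sided exact permutation tests, as were the trimmed-mean factors described below. The smallest p of these tests for 4 against 4 libraries is 0.0286. They were Benjamini-Hochberg adjusted over the library measures compared at each time. Overlaps of called genes were tested with Fisher's exact test.

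Coordinates are those in the deposited tables, on GRCh37. Of the tested genes, 789 (7.50%) overlap another listed gene on the same strand, and their values are uncertain because reads of one locus may have been divided between names. Transcript length and GC content came from GENCODE release 29 sequences, matched by transcript identifier for 99.1% of tested genes, taking the most abundant transcript of each gene.

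Alternatives were: factors by the trimmed mean of M-values computed on the FPKM columns (trims of 30% and 5%), quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter at FPKM 5, robust eBayes, arrayWeights, the replicate letter as a block, only the groups compared, a minimum fold of 1.5, and each library left out in turn. A method for read counts could not be run, since the tables hold FPKM. Added after the data were seen were removal of the trend with transcript length and GC per library (splines with 4 degrees of freedom each), leaving out overlapping genes, leaving out the 3 libraries farthest from their group, and leaving out each library for the interferon and metallothionein lists.

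The steps were tested on simulated data built from each gene's mean over all 24 libraries and its spread within groups, with 200 of 10517 genes changed. For the shares below, noise was drawn independently per gene, without a length and GC trend or correlation between genes. The shares may therefore not hold for the real libraries. At simulated folds of 1.25, 1.5, 2 and 3, the recovered shares were 36%, 74%, 92% and 96% for the 4 h comparison. They were 30%, 70%, 94% and 98% for 24 h, and 38%, 76%, 90% and 94% for 48 h. Unchanged genes made up 4.49%, 5.81% and 5.10% of the simulated calls at 4, 24 and 48 h. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.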

Results

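Transcript levels were measured by paired-end RNA sequencing in HMEC-1, an immortalised line of human dermal microvascular endothelial cells. The cells grew as confluent layers on collagen-coated glass and were left uninfected or exposed to Borrelia burgdorferi, the spirochaete that causes Lyme disease, at a multiplicity of infection of 200 bacteria per cell. Per the labels, RNA came from all cells of a well after 4, 24 or 48 h, with no sorting of cells that carried bacteria; the times are those of the sample titles, and the labels' treatment protocol gives partly different ones. Each of the 6 groups had 4 libraries, and the values are FPKM, so the read depth behind them is unknown. All gene positions are on GRCh37.

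The comparison at 4 h asked how endothelial cells differed from time-matched uninfected cells soon after the bacteria were added. Genes of inflammatory signalling rose. CXCL1 (ENSG00000163739.4_2, chromosome 4, 74735110 to 74736959), a chemokine that attracts neutrophils, measured 10.9 ± 0.77 FPKM in infected wells and 3.06 ± 1.2 FPKM in uninfected wells (mean ± SD, n = 4 each), a log2 fold change of 1.73 ± 0.19 (SE, limma adjusted p = 8.14e-06). CXCL8 (ENSG00000169429.10_2, chromosome 4, 74606223 to 74609433), another neutrophil chemokine, measured 52.4 ± 3.9 against 26.3 ± 3.0 FPKM, a log2 fold change of 0.98 (limma adjusted p = 9.48e-07). CCL2, which attracts monocytes, measured 18.1 ± 1.1 against 8.87 ± 1.5 FPKM (log2 fold change 1.00, limma adjusted p = 2.19e-05). Of 12 tested members of the list of inflammatory cytokines and chemokines 7 rose, and 8 rose adjusted over the list alone; camera gave an adjusted p of 3.2e-07, and 0.00299 with an estimated correlation.

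The NF-κB list at 4 h had 8 of 20 members that rose, and also 8 adjusted over the list alone. TNFAIP3, a feedback inhibitor of NF-κB, measured 5.48 ± 0.38 FPKM in infected and 2.72 ± 0.18 FPKM in uninfected wells, a log2 fold change of 0.89 (limma adjusted p = 8.14e-06). BIRC3 rose by 0.85 and IRAK2 by 0.52 on the log2 scale. The list's camera adjusted p was 0.000808, and the adjusted p was 0.193 with an estimated correlation. The leukocyte adhesion molecule ICAM1 measured 18.6 ± 2.1 against 10.6 ± 2.7 FPKM (log2 fold change 0.81, limma adjusted p = 0.00137), VCAM1 rose by 0.66, and the cytokine IL6 rose by 0.66 on the log2 scale. The inhibitor NFKBIA rose by 0.67 with a limma adjusted p of 0.0261, and this call was lost without infected replicate A, B or D or uninfected replicate D (0.46 to 0.67). In the list of leukocyte adhesion and procoagulant surface genes 3 of 11 members rose and 1 fell, with the same numbers adjusted over the list alone, and camera did not call it (adjusted p = 0.217).

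Large rises at 4 h were also found outside the cytokine and NF-κB lists. ARRDC3 (ENSG00000113369.8_2, chromosome 5, 90664541 to 90679176), an arrestin-domain protein, measured 28.0 ± 5.0 against 7.05 ± 0.97 FPKM, a log2 fold change of 1.91 ± 0.17 (SE, limma adjusted p = 7.36e-07). BHLHE40, a transcription factor of the hypoxia and clock responses, measured 24.2 ± 6.7 against 6.61 ± 0.54 FPKM (log2 fold change 1.76). ADM (ENSG00000148926.9_3, chromosome 11, 10326227 to 10328944), the vasodilator peptide adrenomedullin, measured 18.8 ± 6.3 against 5.68 ± 1.8 FPKM (log2 fold change 1.63, limma adjusted p = 0.000148). In the hypoxia and glycolysis list 9 of 29 members rose and 1 fell, or 12 and 2 adjusted over the list alone. Examples are ANKRD37 with a log2 fold change of 1.11 and the lipase inhibitor ANGPTL4 with 1.10. DDIT4, an inhibitor of mTORC1 from the unfolded protein and amino acid stress list, measured 115 ± 18 against 58.9 ± 6.2 FPKM. GAPDH, a glycolytic enzyme of the hypoxia and glycolysis list often used as a reference gene, was the member that fell, by 0.35 (limma adjusted p = 0.0193); quantile normalization kept its direction and ended the call (−0.19), as did leaving out infected replicate A, C or D or uninfected replicate C (−0.35 to −0.29). The camera adjusted p of the hypoxia and glycolysis list was 0.00321, and the adjusted p was 0.328 with an estimated correlation. NOG, a secreted BMP antagonist, rose by 1.03 on the log2 scale.

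Some genes for cytosolic ribosomal proteins fell at 4 h. RPS29 (ENSG00000213741.9_3, chromosome 14, 50037702 to 50065882) measured 17.4 ± 3.0 FPKM in infected and 28.2 ± 4.2 FPKM in uninfected wells, a log2 fold change of −0.69 (limma adjusted p = 0.00535). Of 46 members 11 fell, and 35 fell adjusted over the list alone; the median log2 fold change was −0.26. The list's camera adjusted p was 1.33e-21, and the adjusted p was 0.193 with an estimated correlation. Transcripts of these genes are short, and across genes the log2 fold change at 4 h ran with transcript length (Spearman's rho 0.479 over genes, which are not independent replicates). KLF2, a transcription factor that fluid flow induces in endothelium, measured 27.2 ± 1.2 against 37.6 ± 2.5 FPKM, a log2 fold change of −0.46 (limma adjusted p = 0.000952). ATF5, a stress-response transcription factor, fell by 0.57 on the log2 scale. CDH5, the adherens junction cadherin of endothelium, measured 28.4 ± 9.1 against 30.8 ± 10 FPKM (log2 fold change −0.10, limma adjusted p = 0.865).

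Further lists moved by camera at 4 h with the preset correlation alone. Proteases and fibrinolysis genes had 5 of 17 members that rose (12 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 9.13e-05 and an adjusted p of 0.116 with an estimated correlation. Extracellular matrix genes had 3 of 30 that rose (6 adjusted over the list alone), with 9.13e-05 and an adjusted p of 0.488 with an estimated correlation. Endothelial junction genes had 5 of 15 that rose (7 adjusted over the list alone), with 0.027 and an adjusted p of 0.327 with an estimated correlation. The list of metallothioneins and zinc genes had 2 of 10 that rose (4 adjusted over the list alone), with 0.0291 and an adjusted p of 0.193 with an estimated correlation. Cholesterol synthesis genes had 1 of 24 that fell, over all genes and adjusted over the list alone, with 0.0107 and an adjusted p of 0.116 with an estimated correlation. Immediate early genes had 5 members that rose and 1 that fell of 19, or 5 and 2 adjusted over the list alone, and the unfolded protein list 3 and 1 of 27, or 7 and 1 adjusted over the list alone. Neither had a camera call (adjusted p = 0.325 and 0.491). Interferon-stimulated genes had 1 of 24 that rose and 1 that fell, also adjusted over the list alone (camera adjusted p = 0.491).

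In all, 646 of 10517 genes passed at 4 h, 455 higher and 191 lower in infected wells, and 91 of them changed at least 1.5-fold. The split by direction moved with scaling: 313 higher and 284 lower with trimmed-mean factors, 293 higher and 238 lower with quantile normalization, and 253 higher and 237 lower after removal of the length and GC trend. The factors themselves ran with infection at 4 h, at 1.017 ± 0.015 in infected and 0.983 ± 0.022 in uninfected libraries (n = 4 each). Their exact permutation p was 0.0286 (Benjamini-Hochberg adjusted p = 0.114). The count was 179 without uninfected replicate C, 205 without infected replicate A, 249 without infected replicate C and 402 without uninfected replicate D, and 148 when only the 4 h groups entered the model, where ICAM1 and RPS29 no longer passed (limma adjusted p = 0.0528 and 0.0513). Uninfected 4 h replicate C stood out among the 24 libraries. It had the lowest trimmed-mean factor (0.950) and the most negative correlation of its deviations with transcript length (rho −0.39). Its mitochondrial share of FPKM was the highest (5.91%). At transcript level 61 of 25667 transcripts passed, 50 higher and 11 lower, with ARRDC3, CXCL8 and BHLHE40 among them, and 55 of their 61 genes also passed as genes.

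**Figure D1:**
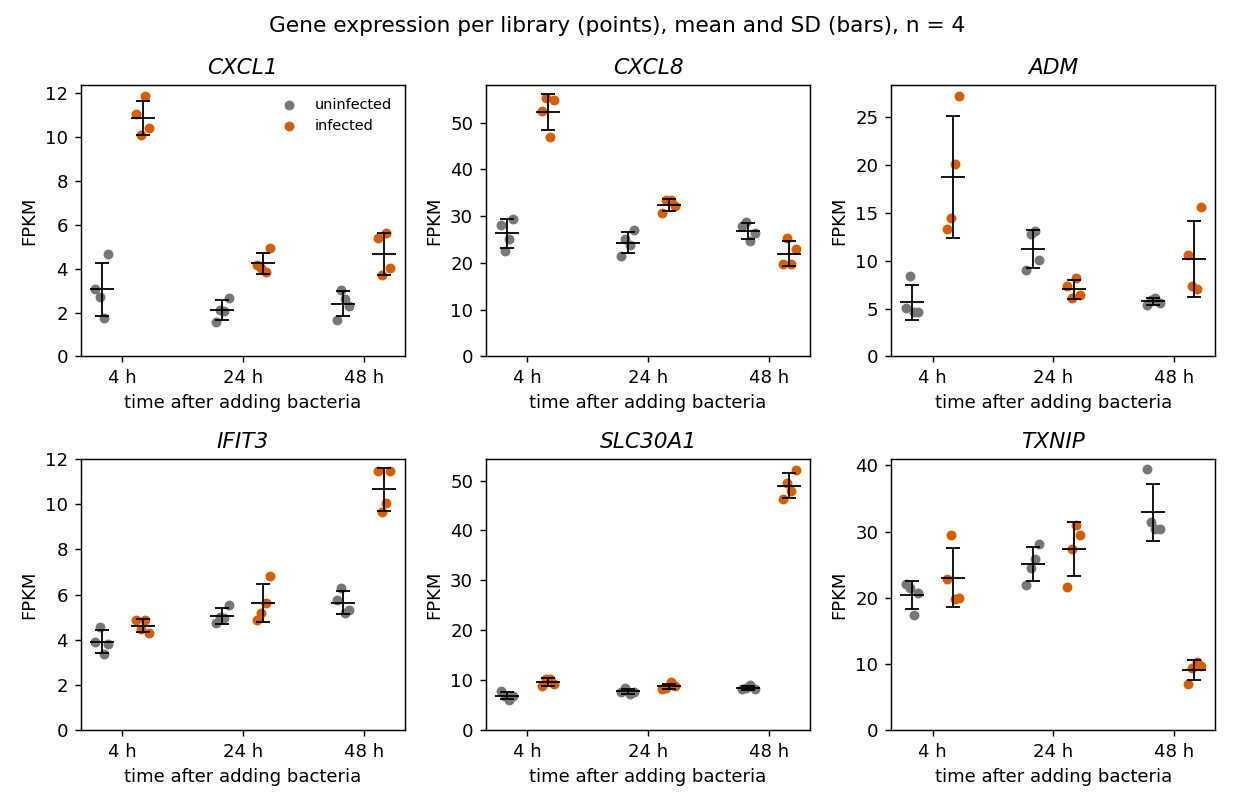
FPKM of 6 genes (vertical axis) in uninfected (grey) and infected (orange) wells at 4, 24 and 48 h, with 1 point per library and bars for mean and SD (n = 4). CXCL1 and CXCL8 stand apart most at 4 h (10.9 against 3.06 and 52.4 against 26.3 FPKM), IFIT3 and SLC30A1 at 48 h (10.7 against 5.65 and 49.0 against 8.54 FPKM), and TXNIP is lower in infected wells at 48 h (9.11 against 32.9 FPKM).

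At 24 h fewer genes differed, and the chemokines were still higher. CCL2 measured 17.1 ± 2.2 FPKM in infected and 10.5 ± 1.5 FPKM in uninfected wells (n = 4 each), a log2 fold change of 0.68 ± 0.12 (SE, limma adjusted p = 0.0139), a call lost without infected replicate B or D or uninfected replicate A or C (0.59 to 0.67). CXCL1 measured 4.24 ± 0.49 against 2.11 ± 0.46 FPKM (log2 fold change 0.87, limma adjusted p = 0.0456) and CXCL8 32.4 ± 1.3 against 24.4 ± 2.3 FPKM (0.41, limma adjusted p = 0.0454); each of these calls was lost without any single library of the 8 except uninfected replicate D (0.77 to 0.92 for CXCL1, 0.35 to 0.44 for CXCL8). The CXCL1 call was also lost with the replicate letter as a block (limma adjusted p = 0.0667), and the CXCL8 call with trimmed-mean factors (limma adjusted p = 0.0507). Of the 12 cytokine and chemokine genes 3 rose, or 7 adjusted over the list alone, with a camera adjusted p of 6.04e-08, and 0.0014 with an estimated correlation. IL6, ICAM1 and TNFAIP3 did not pass, with log2 fold changes of 0.36, 0.27 and 0.08. None of the 20 NF-κB genes passed over all genes, and 1 rose adjusted over the list alone (camera adjusted p = 0.707).

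PDK4 (ENSG00000004799.7_2, chromosome 7, 95212811 to 95225803), a kinase that holds back glucose oxidation, measured 11.1 ± 1.5 against 6.10 ± 0.52 FPKM at 24 h, a log2 fold change of 0.81 (limma adjusted p = 0.00043). SHISA2 rose by 0.74 and the elastic fibre protein FBLN5 by 0.64, a call lost without uninfected replicate A (0.59). Of the YAP/TAZ target genes, which respond to mechanical tension, 2 of 20 fell, or 4 adjusted over the list alone. These were CTGF (ENSG00000118523.5_2, chromosome 6, 132269316 to 132272513) with 190 ± 11 against 250 ± 8.7 FPKM (log2 fold change −0.39, limma adjusted p = 0.000905) and CYR61 with 116 ± 1.2 against 145 ± 2.9 FPKM (−0.32, limma adjusted p = 0.00199), both secreted matricellular proteins. The list's camera adjusted p was 1.78e-05, and the adjusted p was 0.0973 with an estimated correlation. The crosslinking enzyme TGM2 fell by 0.43. GRB2, an adaptor of receptor tyrosine kinases, measured 9.25 ± 1.5 against 29.5 ± 8.4 FPKM (log2 fold change −1.58, limma adjusted p = 0.0176), a call lost without infected replicate B (−1.47) or without uninfected replicate A (−1.48), B (−1.51) or C (−1.50). FHL1, a LIM-domain protein, measured 3.63 ± 0.59 against 10.3 ± 0.80 FPKM (log2 fold change −1.39, limma adjusted p = 0.0469), and its call was lost without any of the 8 libraries (−1.48 to −1.34).

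Among the other lists at 24 h, hypoxia genes had 1 of 29 that fell, over all genes and adjusted over the list alone, with a camera adjusted p of 6.43e-05 and an adjusted p of 0.273 with an estimated correlation. The member was PFKFB3, a regulator of glycolysis, at −0.57, and its call was lost without any single library except infected replicates C and D (−0.62 to −0.43). Metallothioneins had none over all genes and 3 that rose adjusted over the list alone (0.0236; adjusted p = 0.216 with an estimated correlation). Interferon-stimulated genes had none over all genes and 1 that rose adjusted over the list alone (0.0278; adjusted p = 0.421 with an estimated correlation). Ribosomal protein genes had none that passed in either way, with a median log2 fold change of −0.07 and a camera adjusted p of 0.00569 (adjusted p = 0.761 with an estimated correlation).

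In all, 44 of 10517 genes passed at 24 h, 27 higher and 17 lower, and 17 of them changed at least 1.5-fold. Without a single library the count fell to 11 (uninfected replicate A or C), 14 (infected B), 19 (infected D), 23 (uninfected B) or 25 (uninfected D), and it was 4 with only the 24 h groups in the model, where CCL2, PDK4 and CTGF no longer passed (limma adjusted p = 0.148, 0.0567 and 0.073). The split was 23 higher and 23 lower with trimmed-mean factors 37 higher and 36 lower with quantile normalization and 75 higher and 78 lower after trend removal. At an unadjusted p under 0.05 there were 1243 genes, against 526 expected by chance. The 526 is an average without a spread. Genes are not independent of each other, and how far such counts vary around it was not tested. At transcript level 8 passed, 4 in each direction, and 5 of their 8 genes passed as genes; the higher and lower transcripts were 4 and 2 with quantile normalization, and 4 passed without infected replicate B or without uninfected replicate C.

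At 48 h the zinc exporter SLC30A1 (ENSG00000170385.9_2, chromosome 1, 211744910 to 211752084) measured 49.0 ± 2.5 FPKM in infected and 8.54 ± 0.40 FPKM in uninfected wells (n = 4 each), a log2 fold change of 2.45 ± 0.07 (SE, limma adjusted p = 5.19e-16). SLC30A1 was also higher at 4 h, by 0.46 (limma adjusted p = 0.000354; 0.26 after trend removal), and did not pass at 24 h (0.16, limma adjusted p = 0.352). Metallothioneins, small proteins that bind zinc and copper, rose with it: MT1X measured 14.1 ± 3.6 against 6.79 ± 1.1 FPKM (log2 fold change 0.98, limma adjusted p = 0.000364), and MT1F and MT1M rose by 1.08 and 0.81. Of the 10 metallothionein and zinc genes 6 rose and 1 fell, with the same numbers adjusted over the list alone. The camera adjusted p was 1.13e-06, and 0.00415 with an estimated correlation.

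Interferon-stimulated genes rose at 48 h in 15 of 24 members, or 17 adjusted over the list alone, and none fell. IFIT3 (ENSG00000119917.13_2, chromosome 10, 91087651 to 91100728), an antiviral effector, measured 10.7 ± 0.94 against 5.65 ± 0.50 FPKM, a log2 fold change of 0.86 (limma adjusted p = 4.83e-06). IFIT2, IFIT1 and the exonuclease ISG20 rose by 0.84, 0.78 and 0.64. The list's camera adjusted p was 1.14e-13, and 0.00356 with an estimated correlation. In the list of MHC class I presentation 3 of 16 rose, or 4 adjusted over the list alone, with HLA-E at 0.29 and the proteasome subunit PSMB9 at 0.37 on the log2 scale. Its camera adjusted p was 0.000309, and the adjusted p was 0.191 with an estimated correlation.

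Of the cytokine and chemokine genes at 48 h 6 rose and 2 fell, or 7 and 2 adjusted over the list alone. CCL2 measured 27.8 ± 3.7 against 16.1 ± 1.7 FPKM (log2 fold change 0.77, limma adjusted p = 0.000305) and CXCL1 rose by 0.84. CXCL8 was lower in infected wells, at 22.0 ± 2.7 against 26.9 ± 1.7 FPKM (log2 fold change −0.29, limma adjusted p = 0.0346). That call was lost with trimmed-mean factors (−0.27) and without infected replicate A or C or uninfected replicate A, B or D (−0.30 to −0.25). The list's camera adjusted p was 0.00259, and the adjusted p was 0.0587 with an estimated correlation.

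Stress genes moved both ways at 48 h. PPP1R15A, a phosphatase subunit that restores translation after stress, measured 42.4 ± 8.0 against 15.9 ± 1.0 FPKM, a log2 fold change of 1.37 (limma adjusted p = 6.87e-08), and the transcription factor ATF3 rose by 1.05. In the unfolded protein and amino acid stress list 4 of 27 rose, also adjusted over the list alone (camera adjusted p = 0.00614; adjusted p = 0.191 with an estimated correlation). The splicing factor SRSF5 rose by 1.31 and the kinase CLK2, which phosphorylates such factors, fell by 0.80. In the heat shock list 6 of 16 fell, or 7 adjusted over the list alone, among them the chaperone HSPA8 with 194 ± 4.6 against 263 ± 33 FPKM (log2 fold change −0.43, limma adjusted p = 0.000518) and CHORDC1 at −0.52. Its camera adjusted p was 0.00614, and the adjusted p was 0.191 with an estimated correlation.

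At 48 h a fall was found for TXNIP (ENSG00000265972.5_2, chromosome 1, 145438469 to 145442635), an inhibitor of thioredoxin and of glucose uptake. It measured 9.11 ± 1.5 FPKM in infected and 32.9 ± 4.3 FPKM in uninfected wells, a log2 fold change of −1.80 ± 0.14 (SE, limma adjusted p = 2.12e-08). PDK4 measured 2.31 ± 0.29 against 6.92 ± 0.46 FPKM (−1.41, limma adjusted p = 7.32e-09) and ARRDC3 2.79 ± 0.25 against 8.14 ± 0.59 FPKM (−1.39, limma adjusted p = 1.25e-05). The immediate early gene EGR1 measured 1.92 ± 0.35 against 5.21 ± 0.39 FPKM (−1.25, limma adjusted p = 1.39e-06). The tight junction gene CLDN5 rose by 0.85 and the endothelial surface gene CLEC14A by 0.56, whereas CDH5 (log2 fold change 0.02), CTGF (−0.04) and GAPDH (0.01) did not pass. The YAP/TAZ target CYR61, which was lower in infected wells at 24 h, passed in the opposite direction at 48 h. ISY1-RAB43, a readthrough gene, was listed at 0 in infected replicates B, C and D and at 1.64 FPKM in infected replicate A, against 1.69, 4.65, 4.82 and 4.76 FPKM in uninfected replicates A to D (limma adjusted p = 0.0319). It overlaps ISY1 and RAB43 on the same strand, so its value is uncertain, and its call was lost without any single library except the A replicates (limma adjusted p from 0.0706 to 0.0842).

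In the remaining lists at 48 h, focal adhesion and actomyosin genes had 5 of 39 that fell, also adjusted over the list alone (camera adjusted p = 0.0355; adjusted p = 0.292 with an estimated correlation). Immediate early genes had 4 of 19 that rose and 1 that fell, or 5 and 1 adjusted over the list alone (0.0193; adjusted p = 0.191 with an estimated correlation). The leukocyte adhesion list had 3 of 11 that rose and 1 that fell, or 4 and 1 adjusted over the list alone (0.0355; adjusted p = 0.144 with an estimated correlation). Replication-dependent histones had 1 of 41 that rose and none adjusted over the list alone (0.00351; adjusted p = 0.586 with an estimated correlation). No ribosomal protein gene of 46 passed in either way, with a median log2 fold change of 0.11 (0.000398; adjusted p = 0.659 with an estimated correlation). Cell cycle genes had 2 of 36 that rose and 6 that fell, or 4 and 8 adjusted over the list alone, and endothelial identity genes 5 and 2 of 24, or 6 and 3 adjusted over the list alone. NRF2 targets had 1 and 1 of 20 and bacterial sensing genes 1 and 1 of 18, also adjusted over the list alone, and none of these lists had a camera call (adjusted p = 0.642, 0.18, 0.81 and 0.704). None of the 13 mitochondrially encoded genes passed, also adjusted over the list alone (0.838).

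Markers of other cell types were tested in the same way. None of the 4 tested lymphatic endothelial markers, the 7 fibroblast and mural cell markers or the 1 leukocyte and red cell marker passed at any time between infected and uninfected wells, over all genes or adjusted over the list alone. The 48 h camera adjusted p-values of these lists were 0.591, 0.574 and 0.884. Of 6 keratinocyte and epithelial markers KRT10 alone passed, over all genes and adjusted over the list alone, with a log2 fold change of −0.36 at 4 h and 0.55 at 48 h.

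In all, 1281 of 10517 genes passed at 48 h, 461 higher and 820 lower, and 138 of them changed at least 1.5-fold. After trend removal the split was 692 higher and 850 lower. The trimmed-mean factors ran with infection in the opposite direction to 4 h, at 0.991 ± 0.0017 in infected and 1.005 ± 0.0095 in uninfected libraries (n = 4 each). Their exact permutation p was 0.0286 (Benjamini-Hochberg adjusted p = 0.0857). The count was 839 without uninfected replicate B, 775 with a minimum FPKM of 5 and 807 with only the 48 h groups in the model. Across genes the log2 fold change ran against transcript length (rho −0.329). At transcript level 220 passed, 92 higher and 128 lower, and of the 215 of their genes that were tested 190 passed as genes. Leaving out any single library lowered the transcript count, from 101 without uninfected replicate B to 154 without infected replicate A.

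**Figure D2:**
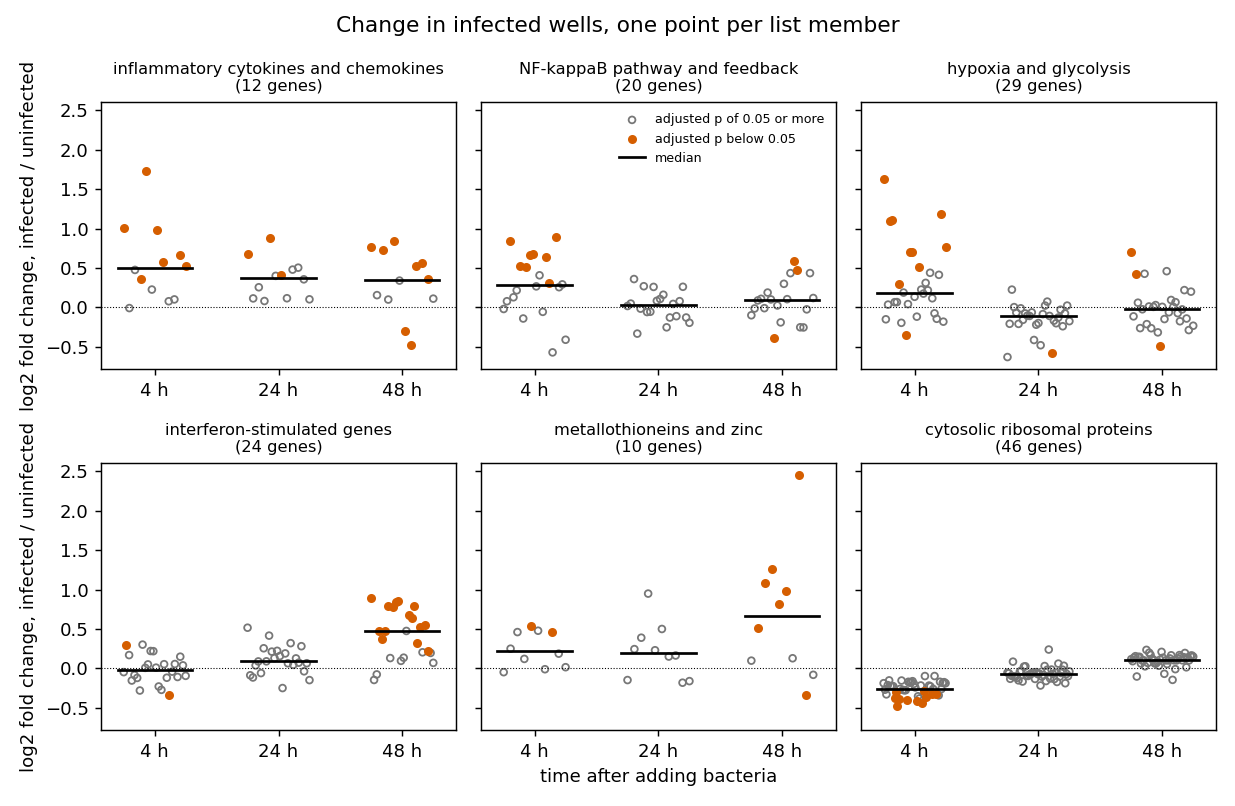
Log2 fold change of infected over uninfected wells (vertical axis) at 4, 24 and 48 h for each tested member of 6 gene lists, with orange points for members with a limma adjusted p under 0.05 and black lines for the median. Cytokines stand highest at 4 h, with 7 of 12 passing, 15 of 24 interferon-stimulated genes and 6 of 10 metallothionein and zinc genes pass upward at 48 h, and 11 of 46 ribosomal protein genes pass downward at 4 h.

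Time comparisons within each arm asked how levels changed as cultures aged with and without bacteria. In infected wells APLN, a vascular peptide, rose by 1.13 from 4 h to 24 h and by 2.26 from 4 h to 48 h on the log2 scale, and in uninfected wells by 0.96 and 1.13. In infected wells at 24 h NOG fell by 1.79, ARRDC3 by 1.37, TNFAIP3 by 1.04 and CXCL8 by 0.68 from their level at 4 h. By 48 h ARRDC3 had fallen by 3.10, PDK4 by 1.98, LIPG, an endothelial lipase, by 1.97 and CXCL8 by 1.24, whereas CLDN5 and IFIT2 had risen by 1.40 and 1.30. In uninfected wells CXCL8 did not pass at either time (log2 fold change −0.11 at 24 h and 0.04 at 48 h), and CLIC3 fell by 1.32 and 1.50. CCL2 rose by 0.83 in uninfected wells by 48 h, so its background level was not constant.

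Lists followed in the same comparisons. In infected wells at 48 h against 4 h, 19 of 24 interferon-stimulated genes rose, also adjusted over the list alone (camera adjusted p = 5.86e-13, and 0.00533 with an estimated correlation). In uninfected wells 11 rose and 1 fell, also adjusted over the list alone (0.00113; adjusted p = 0.443 with an estimated correlation). Of the 46 ribosomal protein genes 40 rose in infected wells, or 42 adjusted over the list alone (1.78e-15; adjusted p = 0.312 with an estimated correlation). Of 16 MHC class I presentation genes 11 rose, also adjusted over the list alone (3.4e-06; adjusted p = 0.109 with an estimated correlation). At 24 h against 4 h in infected wells 8 of 24 cholesterol synthesis genes rose, or 9 rose and 1 fell adjusted over the list alone (0.000124, and 0.0231 with an estimated correlation). In uninfected wells at 24 h 7 of 29 hypoxia genes rose, or 13 adjusted over the list alone (1.2e-07; adjusted p = 0.363 with an estimated correlation), with ADM at 0.95, a call lost without 4 h replicate C or D or 24 h replicate B or C (0.87 to 0.88).

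The numbers of genes that passed were 1575 (684 higher, 891 lower) at 24 h and 3824 (1551 higher, 2273 lower) at 48 h in infected wells, each against 4 h. In uninfected wells they were 466 (306 higher, 160 lower) and 950 (602 higher, 348 lower). With trimmed-mean factors the uninfected splits were 269 higher and 234 lower at 24 h and 496 and 481 at 48 h, and with quantile normalization 263 and 241, and 502 and 449. After trend removal the direction of the larger part turned for uninfected wells at 24 h (422 higher, 464 lower) and 48 h (642 higher, 743 lower) and for infected wells at 24 h (959 higher, 900 lower). Leaving out infected 24 h replicate B, infected 4 h replicate A or infected 4 h replicate C took the infected 24 h count to 816, 943 or 995. The uninfected 24 h count was 255 without 24 h replicate D, 269 without 24 h replicate C and 293 without 4 h replicate D, and the uninfected 48 h count 618, 624 and 630 without 48 h replicate C, 48 h replicate B and 4 h replicate C.

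The test of infection by time asked whether the infection effect at 24 h or 48 h differed from that at 4 h. At 24 h the effect on ADM was lower by a log2 difference of −2.25, on BHLHE40 by −2.09, on ARRDC3 by −2.00 and on TNFAIP3 by −0.81 (limma adjusted p = 0.000551 for ADM). At 48 h the effect on SLC30A1 was higher by 1.99 and on the growth factor BMP4 by 1.39, and lower for ARRDC3 by −3.30, PDK4 by −2.21, TXNIP by −1.96 and CXCL8 by −1.28. The effect on CCL2 did not differ past the threshold (−0.32 at 24 h and −0.23 at 48 h; limma adjusted p = 0.393 and 0.373). Of 29 hypoxia genes 8 were lower at 24 h, or 14 adjusted over the list alone (camera adjusted p = 1.06e-07; adjusted p = 0.198 with an estimated correlation). Of 24 interferon-stimulated genes 14 were higher and 1 lower at 48 h, or 14 and 2 adjusted over the list alone (1.28e-08, and 0.0379 with an estimated correlation). Of 46 ribosomal protein genes 18 were higher at 48 h, or 36 adjusted over the list alone (2.58e-16; adjusted p = 0.339 with an estimated correlation).

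In all, 102 genes passed for 24 h (14 higher, 88 lower) and 1721 for 48 h (497 higher, 1224 lower). With trimmed-mean factors the 48 h split was 732 higher and 890 lower with quantile normalization 612 and 883, and after trend removal 548 and 616. The 24 h split was 29 higher and 84 lower after trend removal. The 24 h count was 47 without uninfected 24 h replicate D, 49 without uninfected 24 h C, 50 without uninfected 4 h C, 51 without infected 24 h B and 56 without infected 4 h A. The 48 h count was 1130 without uninfected 48 h replicate B and 1147 without uninfected 4 h replicate C.

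**Figure D3:**
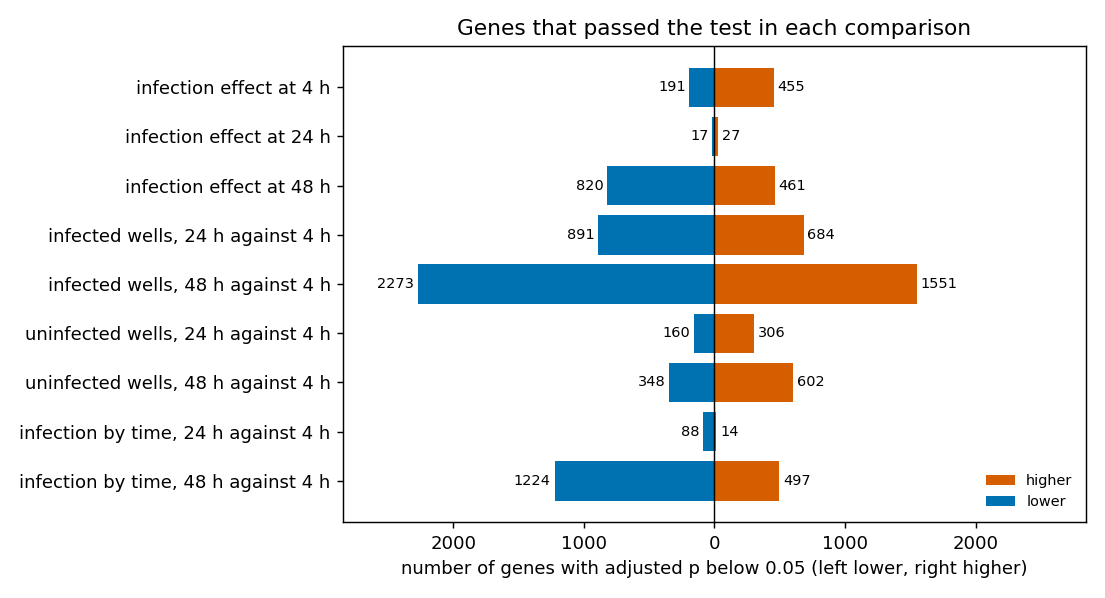
Number of genes with a limma adjusted p under 0.05 (horizontal axis) that were higher (orange, right) or lower (blue, left) in each of the 9 comparisons. The bars run from 27 higher and 17 lower for infection at 24 h to 1551 higher and 2273 lower for infected wells at 48 h against 4 h.

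Overlaps of calls at different times were larger than for independent lists in some pairs and smaller in 1. Of the genes higher in infected wells at 4 h, 10 were also higher at 24 h, where independent lists would share 1.17 (Fisher's exact p = 9.05e-08), and 41 were also higher at 48 h, where independent lists would share 19.9 (Fisher's exact p = 1.02e-05). CXCL1, CCL2 and SHISA2 were higher at all 3 times. CXCL8 and PDK4 were higher at 4 h and 24 h and lower at 48 h. At 24 h the calls of CXCL1, CCL2 and CXCL8 were lost without any of 7, 4 and 7 single libraries. The 48 h call of CXCL8 was lost without any of 5 single libraries. Of the genes higher at 4 h, 91 were lower at 48 h, where independent lists would share 35.5 (Fisher's exact p = 1.32e-17), with ARRDC3 and NFKB1 among them. Of the genes higher at 24 h, 10 were higher at 48 h, where independent lists would share 1.18 (Fisher's exact p = 1.02e-07). Of the genes lower at 4 h, only 6 were lower at 48 h, where independent lists would share 14.9 (Fisher's exact p = 0.0133). Genes are not independent of each other, so these p-values are too small. The comparisons also share the estimate of the spread per gene, so genes with a small spread pass more easily in both. This further lowers the p-values of the larger overlaps, but works against the smaller overlap of 6 genes. In all, 12 such overlaps were tested. The Benjamini-Hochberg adjusted values were 4.09e-07, 3.06e-05, 1.58e-16, 4.09e-07 and 0.0319, and the remaining overlaps did not pass.

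The gene lists that the authors deposited for 6 of the comparisons hold 971 entries, of which 802 (82.6%) passed here in the same direction. For infection at 4 h these were 64 of 78 higher and 7 of 18 lower genes, at 24 h 7 of 22 and 3 of 20, and at 48 h 51 of 67 and 31 of 44. For infected wells against 4 h they were 21 of 27 and 97 of 113 at 24 h, and 167 of 171 and 322 of 339 at 48 h. For uninfected wells at 24 h against 4 h they were 12 of 37 and 20 of 35. The total thus rests largely on infected wells at 48 h, and both sides used the same libraries. The deposited lists rest on an unadjusted p-value and a minimum fold, and the counts here on an adjusted p.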

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

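Of the tests below, the removal of the trend with transcript length and GC, the comparison of ribosomal protein shares and the shuffles of infection labels within each time were chosen after the result they bear on was seen.

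In 9 of 68 groups of 4 libraries tested for the named genes, 1 library lay far from the other 3, where chance gives about 1 in 20 groups, or 3.4. ADM in uninfected 4 h replicate B stood at 8.42 FPKM, with the others at 4.62 to 5.05. CYR61 in uninfected 24 h replicate A stood at 141 FPKM, with the others at 146 to 147. FHL1 in infected 24 h replicate D stood at 4.51 FPKM, with the others at 3.26 to 3.40, and GRB2 in uninfected 24 h replicate D at 16.9 FPKM, with the others at 33.0 to 34.9. ISY1-RAB43 stood at 1.64 FPKM in infected 48 h replicate A, with the others listed at 0, and at 1.69 FPKM in uninfected 48 h replicate A, with the others at 4.65 to 4.82. MT1X in uninfected 48 h replicate D stood at 8.36 FPKM, with the others at 6.04 to 6.38. PPP1R15A in infected 48 h replicate A stood at 54.3 FPKM, with the others at 38.1 to 38.8, and TXNIP in uninfected 48 h replicate A at 39.4 FPKM, with the others at 30.4 to 31.4.

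The infection effect at 24 h differed from that at 4 h for 102 genes by the test of infection by time. Named genes with a higher effect at 24 h, as log2 differences, were ATF5 at 0.89, PLAC9 at 0.87 and KLF2 at 0.57. Those with a lower effect included SLC7A5 at −0.33, NFKB1 at −0.56, CXCL8 at −0.57, DUSP1 at −0.58, THBS1 at −0.58, IRAK2 at −0.59, TNFAIP3 at −0.81, NOG at −1.09 and ERRFI1 at −1.18. Further genes with a lower effect were DDIT4 at −0.75, PFKFB3 at −0.79, KDM3A at −0.92, ANGPTL4 at −1.10, HK2 at −1.11, ANKRD37 at −1.17, BHLHE40 at −2.09 and ADM at −2.25, with ARRDC3 at −2.00. C10orf10, chosen after its values were seen, stood at −2.82. Of these calls, that of CXCL8 was lost without any of 9 libraries (infected 4 h A, B and D, infected 24 h A and B, uninfected 4 h C, uninfected 24 h B, C and D; −0.59 to −0.53). The PLAC9 call was lost without any of 10 libraries (infected 4 h A, B and C, infected 24 h A and B, uninfected 4 h C and D, uninfected 24 h B, C and D; 0.76 to 0.91). The HK2 call was lost without any of 6 libraries (infected 24 h A and B, uninfected 4 h C and D, uninfected 24 h C and D; −1.12 to −0.996).

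At 48 h the infection effect differed from that at 4 h for 1721 genes. Higher log2 differences were found for RAB43 at 2.98, SLC30A1 at 1.99, BMP4 at 1.39, FAM43A at 1.20, PPP1R15A at 1.10, SRSF5 at 1.06, SLC37A4 at 1.06, ATF3 at 0.94, ATF5 at 0.89, CLDN5 at 0.82, ENC1 at 0.82, FABP4 at 0.69, SLC3A2 at 0.64, MT1F at 0.62, KLF2 at 0.52, CLEC14A at 0.38, ATF4 at 0.36, GAPDH at 0.36 and CYR61 at 0.30. RAB43 shares its locus with ISY1-RAB43 and is uncertain. Interferon-stimulated and presentation genes with a higher effect were IFIT2 at 0.79, IFIT1 at 0.77, IFIT3 at 0.64, ISG20 at 0.58, PSMB9 at 0.48 and HLA-E at 0.30. Ribosomal protein genes with a higher effect were RPS29 at 0.70, RPS28 at 0.67, RPL3 at 0.62 and RPL38 at 0.47.

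Lower log2 differences at 48 h were found for IRAK2 at −0.31, IER3 at −0.34, DUSP1 at −0.46, BIRC3 at −0.76, NFKBIA at −0.86, CXCL1 at −0.89, NFKB1 at −0.90, TNFAIP3 at −1.15 and CXCL8 at −1.28. The heat shock genes HSPH1 and CHORDC1 stood at −0.54 and −0.65, and THBS1 at −0.58. Further genes were STC1 at −0.91, DDIT4 at −1.02, NOG at −1.03, ANGPTL4 at −1.04, CLK2 at −1.04, KDM3A at −1.19, EGR1 at −1.27, PIM1 at −1.29, ANKRD37 at −1.37, EDN2 at −1.42, SLC2A3 at −1.48, BHLHE40 at −1.84, TXNIP at −1.96, PDK4 at −2.21, C10orf10 at −2.51 and ARRDC3 at −3.30.

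Other splits of the same libraries were used to ask whether an arbitrary grouping gives as many genes. For each comparison of 4 with 4 libraries the real split alone, 1 of 35, reached its count, the smallest share this test can give. This argues against an arbitrary grouping of these libraries, without adjustment over the comparisons. Splits that mix the groups add any real difference to the spread, so low counts for them were likely in advance. The test cannot tell infection or time from any other difference between the wells compared. For infection the real counts were 646, 44 and 1281 genes at 4, 24 and 48 h and the highest of the other splits gave 1, 2 and 1. For transcripts the real counts were 61, 8 and 220 and the highest of the others gave 2 each. For time in infected wells they were 1575 and 3824, with 2 and 860 as the highest of the others, and in uninfected wells 466 and 950, with 2 and 1.

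Infection by time was tested with 100 splits that shuffled time labels within infected and within uninfected libraries. As many genes came from 3 of 100 splits for 24 h (102 genes, highest other split 487) and from 3 of 100 for 48 h (1721 genes, highest other split 2425). The other 2 splits as large in each case parted the infected libraries by time, which points to a structure of the samples, but 1 further split for 24 h that also parted them gave only 17 genes. A first draw that did not merge mirrored splits had given 3 of 100 (highest other 487) and 5 of 100 (highest other 2514), and 5 of 100 is not under 0.05. The draws differed in their splits as well as in this merging, so what moved the count was not separated. For 48 h the result with shuffled time labels is therefore uncertain. With infection labels shuffled within each time, 4 of 100 splits gave as many genes for 24 h, with 1815 as the highest, many times the real count, and 1 of 100 for 48 h, with 942 as the highest of the others. For 24 h some splits thus exceeded the real count under both shuffles, so that count is uncertain too.

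Of 46 ribosomal protein genes 11 were lower in infected wells at 4 h, and transcripts of these genes are short. After the trend with transcript length and GC was removed, the median log2 fold change went from −0.26 to −0.18 and the number of genes that fell from 11 to 9. The camera adjusted p was then 1.26e-12 with the preset correlation and 0.199 with an estimated correlation, which had been 0.193 before, so the call under the second setting was absent both before and after. The ribosomal protein share of FPKM was 8.11 ± 0.51% in infected and 9.36 ± 0.61% in uninfected wells at 4 h (n = 4 each, exact permutation p = 0.0571, Benjamini-Hochberg adjusted p = 0.114). A length trend of the libraries and a lower level of these transcripts cannot be told apart here, because the trend itself runs with the groups and the libraries are few.

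Genes higher in infected wells at 4 h were over-represented among those lower at 48 h, with 91 shared where independent lists would share 35.5. The transcript length trend ran in opposite directions at 4 h and 48 h and might produce such an exchange. After its removal 44 genes were shared where independent lists would share 20.6 (Fisher's exact p = 1.18e-06 over genes, which are not independent), and 35 were shared under both settings, which argues against the trend as the whole cause. Across genes the rank correlation of the effects at 4 h and 48 h went from −0.22 to −0.03, so most of the relation across all genes was lost with the trend. Overlapping loci held 0% of the 91 genes. Both comparisons used the same estimate of the spread per gene, so genes with a small spread pass more easily in both. Independent lists are therefore not a strict baseline, and genes higher at both times also exceeded it, with 41 shared against 19.9. The part of the shared spread in the 91 genes was not separated, and a biological exchange stays a hypothesis.

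Of 24 interferon-stimulated genes 15, and of 10 metallothionein and zinc genes 6, were higher in infected wells at 48 h. After removal of the length and GC trend 17 interferon-stimulated genes passed upward, against 15 before, and 6 metallothionein and zinc genes, against 6 before. Leaving out 1 library at a time gave at least 13 interferon-stimulated genes (without uninfected 48 h replicate C) and 6 of 6 metallothionein and zinc genes. A single library or the trend therefore did not give these counts, and a response of infected wells to bacteria, to interferon or to zinc may underlie them as a hypothesis that these data did not test further.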

How the results depend on the processing

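The removal of the length and GC trend, the fit without overlapping genes, the fit without the 3 libraries farthest from their group (infected 48 h A, infected 24 h A and uninfected 4 h B) and the leaving out of libraries for the interferon and metallothionein lists were chosen after the data were seen.

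Of 170 results for named genes, 151 passed. Of these, 110 passed under every alternative in which their gene was tested, other than a minimum fold of 1.5. Not every gene was tested in each: the filter at FPKM 5 kept 116 of the 151 results, and leaving out overlapping genes kept 149. None of the 151 changed direction in any alternative, whereas 7 of the 19 that did not pass changed sign in at least 1: CTGF and CDH5 at 4 h, FN1 and ACTB at 24 h, and CDH5, GAPDH and ACTB at 48 h. Counts of genes moved more. With only the groups compared in the model, which leaves fewer libraries to estimate the spread, the counts were 148 at 4 h, 4 at 24 h and 807 at 48 h for infection. They were 614 for infected wells at 24 h, 89 and 428 for uninfected wells at 24 h and 48 h, 48 for infection by time at 24 h, and 20, 14 and 35 for transcripts at 4, 24 and 48 h. With arrayWeights they were 1201 at 4 h, 95 at 24 h, 919 for uninfected wells at 24 h, 168 for infection by time at 24 h, and 97 and 13 transcripts at 4 h and 24 h. Without the 3 farthest libraries they were 1060 at 4 h, 93 at 24 h, 219 for infection by time at 24 h and 13 transcripts at 24 h. After trend removal they were 153 at 24 h and 886 for uninfected wells at 24 h, and quantile normalization gave 73 at 24 h. The filter at FPKM 5, which leaves fewer genes, gave 775 at 48 h, 2510 for infected and 631 for uninfected wells at 48 h against 4 h, and 14 transcripts at 24 h. For infection at 48 h the split was 535 higher and 762 lower with trimmed-mean factors and 523 and 805 with quantile normalization. For infected wells at 48 h against 4 h it was 1817 higher and 2024 lower with trimmed-mean factors, 1766 and 2028 with quantile normalization, and 1825 and 1906, near even, after trend removal. For the other changes the cause was not tested.

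A minimum fold of 1.5, which by construction removes small changes, left 91, 17 and 138 genes for infection at 4, 24 and 48 h, 170 and 711 for infected and 49 and 106 for uninfected wells at 24 h and 48 h, 50 and 549 for infection by time, and 5 and 115 transcripts at 24 h and 48 h. Leaving out 1 library at a time gave 179 to 896 genes at 4 h, 11 to 46 at 24 h and 839 to 1114 at 48 h for infection. It gave 816 to 1516 and 3164 to 3773 for infected wells, 255 to 443 and 618 to 1045 for uninfected wells, 47 to 139 and 1130 to 2030 for infection by time, and 25 to 68, 4 to 12 and 101 to 154 transcripts.

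With an estimated correlation 8 of the 74 calls of fixed gene lists held: cytokines at 4 h and 24 h, metallothioneins at 48 h, interferon-stimulated genes at 48 h, in infected wells over time and in infection by time, and cholesterol synthesis in infected wells at 24 h and in infection by time at 24 h. Replication-dependent histones in infection by time at 48 h went from a median of 0.16 to −0.11 after trend removal; the cause was not tested.

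With the replicate letter as a block (replicate block) the counts were 457, 32 and 1162 for infection, 1377 and 3693 for infected and 380 and 823 for uninfected wells, 74 and 1486 for infection by time, and 43, 6 and 138 transcripts. Of the named results that passed, 6 lost their call under the block. Among them were CXCL1, FHL1 and PFKFB3 for infection at 24 h (limma adjusted p = 0.0667, 0.0662 and 0.0541). Libraries with the same letter did not deviate together on average, with a mean correlation of −0.01 against 0.004 for different letters. Of 12 infected and uninfected pairs 1 had a correlation over 0.1 (range −0.20 to 0.30). It was the A pair at 24 h (0.30), so a deviation shared by these A libraries is not excluded. Of 24 libraries 5 correlated best with their own letter. An alternative that needs read counts was not run, since the tables hold FPKM, and the unknown depth leaves counting error unmeasured for low genes.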

Other observations

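The 6 gene lists described here, the genes named from them and CYP1B1 and CYP1A1 were chosen after values were seen, so their p-values are not independent evidence; the tests of FOXO and glucocorticoid receptor targets were written down before their results were seen.

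Targets of the aryl hydrocarbon receptor, a sensor of small aromatic molecules, were in part higher in infected wells. The cytochrome CYP1B1 rose by 1.23, 0.82 and 1.09 on the log2 scale at 4, 24 and 48 h, and CYP1A1 by 0.90, 0.74 and 0.61 (n = 4 each). Of 6 tested targets 3, 2 and 3 rose, with camera adjusted p = 0.00933, 0.0188 and 0.00342, and adjusted p = 0.0312, 0.0627 and 0.0215 with an estimated correlation. Targets of BMP and TGF-β signalling rose in 7 of 14 members at 4 h, among them NOG at 1.03, the inhibitory SMAD7 at 0.90 and PMEPA1 at 0.80 (camera adjusted p = 3.11e-06, and 0.00581 with an estimated correlation). At 48 h 4 of them fell, among them ID1 by 0.68 and SMAD9 by 0.61 (0.000858, and 0.0215 with an estimated correlation). The difference between the infection effects at 48 h and 4 h was lower for 8 of the 14 (5.83e-07, and 0.00336 with an estimated correlation). In uninfected wells 8 and 7 of them also fell from 4 h to 24 h and 48 h, so these genes move with culture time without bacteria.

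Targets of p53 rose in 7 of 23 members at 48 h in infected wells, with TP53INP1 at 0.64, PHLDA3 at 0.62 and ZMAT3 at 0.58 (camera adjusted p = 0.000112, and 0.0215 with an estimated correlation). From 4 h to 48 h, 17 of them rose and 1 fell in infected wells and 10 rose in uninfected wells. The difference between the infection effects at 48 h and 4 h was called for the list (0.00581; adjusted p = 0.131 with an estimated correlation). Splicing factors went both ways at 48 h, with 4 of 23 higher and 5 lower (camera adjusted p = 0.205), among them SRSF5 at 1.31 and SRSF6 at 0.83, whereas RSRC2 fell by 0.74.

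TXNIP, ARRDC3 and PDK4, which were lower in infected wells at 48 h, include known targets of FOXO factors, such as PDK4, which is also a target of the glucocorticoid receptor, whose ligand hydrocortisone was in the medium per the labels. Lower activity of either might lower the other targets too. The 12 other FOXO targets tested had a median log2 fold change of 0.03 at 48 h (camera adjusted p = 0.670, and 0.853 with an estimated correlation). The 10 other glucocorticoid receptor targets had a median of 0.05 (0.883, and 0.909 with an estimated correlation). Of the FOXO targets 1 rose, 2 fell and 9 did not pass. Of the glucocorticoid receptor targets none rose, 2 fell and 8 did not pass. Since most members of both lists did not pass and neither list was called, neither explanation is supported or excluded.

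The FPKM of RAB43, ISY1-RAB43 and ISY1, which overlap on the same strand, summed to 18.4 ± 1.6 in infected and 20.2 ± 1.1 in uninfected wells at 4 h, 21.2 ± 0.70 and 19.4 ± 1.7 at 24 h, and 21.4 ± 1.1 and 16.0 ± 2.5 at 48 h (n = 4 each); the sums were not tested.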
